A study of Mus musculus with 6 samples.

How the data were processed

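RNA from cell pellets of proliferating and senescent mouse hepatic stellate cells was hybridised to Affymetrix 3' expression arrays, 3 per group, after extraction with Trizol and biotin labelling, per the labels' protocols. The deposited values are log2 expression values per probe set, made by the authors with RMA (robust multi-array average), per the submitters' processing notes. RMA corrects background, forces the arrays to one distribution of values (quantile normalization) and summarises the probes of each set. The version, software, chip description, filters and batches are not given in the sources used here, and batches were not analysed here. The values behaved as quantile normalized values do, since the sorted values of the 6 arrays differed by at most 0.123 log2 units at any rank. Such normalization removes any shift shared by most genes, so every change is relative to the other genes on the array. RMA also compresses changes of dim and very bright probe sets. No array was left out, and no pair of arrays held identical values.

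Of 45101 probe sets, 64 are control probe sets. A platform annotation table paired 34958 probe sets with 1 gene symbol and 932 with several, and 9211 were not listed with a gene, of which 9160 were not controls. Symbols were updated through the Entrez gene number with a RefSeq table of assembly GRCm38.p6, which held the number of 34754 probe sets and not of the other 204, whose symbols were kept. No genome build is stated for the probes, so no coordinates are given. Probe sets with several genes or none were named nowhere. Each of the 18194 genes was read from its probe set with the highest mean over the 6 arrays, which matters for the 9012 genes with more than 1. For 1599 genes that probe set is of a type that can bind several transcripts (suffix _s_at or _x_at), so reads of close relatives are uncertain. Among unnamed probe sets, 566 passed the threshold in a fit over all probe sets.

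The groups were taken from the sample titles. Genes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, senescent minus proliferating, without covariates, and p-values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. The median standard error of a change was 0.0884 log2 units, with 4 residual and 4.21 prior degrees of freedom. Data were simulated with the real genes' means and eBayes-moderated spreads, as normal noise independent between genes (18194 genes, senescent against proliferating). The fit recovered 79.1% of 67 genes changed by 0.5 log2 units, 100% of 67 changed by 1 and 100% of 66 changed by 2. A further list of genes was shifted by 0.4, and calls of its members were not counted as false. The fit made 16 false calls among 218. Far fewer genes were changed here than were called in the data, and real arrays may depart from these assumptions. The rates therefore need not carry over to the real arrays. No detection calls were used, so background was taken as the 95th percentile of the means of 44 olfactory receptor probe sets, 5.57 log2 units, which 12501 genes and 3430 of the called genes exceeded. Where all arrays of 1 group were below it, the fold is given as a bound for the probe set read, the brighter group's mean against 5.57. Control probe sets were averaged per array and compared with an exact two-sided permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

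The following choices were made before the data were examined. There were 26 gene lists. The primary ones were cell division, DNA replication, p53 target genes, secretory phenotype, fibrillar and basement membrane matrix, and stellate cell activation and contraction. The secondary ones were matrix degradation, quiescent stellate cells, interferon response, NF-kB targets, antigen presentation and natural killer cell ligands, lysosome, amino acid and integrated stress response, respiratory chain, cholesterol synthesis, homologous recombination and Fanconi repair, and senescence regulators. Marker lists covered hepatocytes, macrophages, endothelial cells, biliary cells, lymphocytes, neutrophils, mesothelial cells, portal fibroblasts and vascular smooth muscle. Some genes belong to 2 lists, and listed genes without a probe set of their own were not analysed here. Lists were tested with camera at a preset correlation of 0.01, with p-values adjusted over the 26 lists. The genes named are the hairpin's target (not analysed here), Cdkn1a, Mdm2, Cdkn2a and Glb1, the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups do not overlap, leaving out unnamed clones, up to 4 called members per list by size of change, up to 2 called against the list's median, the 2 brightest members of a list with fewer than 2 calls, the measured senescence regulators and the sex-linked genes. Members named beyond this, where 5 or fewer of a list rose or fell, were chosen after their values were seen.

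Alternatives covered the probe sets per gene, testing probe sets, filters on dim genes, the variance prior, cyclic loess and median centring, array weights, the replicate number as a block, leaving out each array, tests without moderation and against a 1.5-fold change, an estimated correlation, fry, and list members above the median level. Scaling to the poly-A spike-ins, and restricting 3 further lists to members above background, were added after seeing the data.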

Results

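Gene expression was measured with Affymetrix mouse arrays in hepatic stellate cells, which in the healthy liver are pericytes that store vitamin A and after injury turn into matrix-producing myofibroblasts. All samples carried a transgene in which doxycycline switches on a short hairpin RNA against p53 together with a green fluorescent marker. The proliferating group (3 arrays) received doxycycline at 1 ug/ml and is labelled as having p53 knocked down. The senescent group (3 arrays) is labelled as untreated control cells with p53 expressed. The transcript that the hairpin targets is not analysed here. Each array gave log2 values for 45101 probe sets, and array medians lay between 6.15 and 6.19. Pearson correlations across probe sets, which are not independent replicates, were 0.995 to 0.997 between arrays of a group and 0.989 to 0.992 between groups. The first principal component held 68.1% of the variance and separated the groups. On the second, with 12.4%, proliferating replicate 1 lay at 17.7 and the other arrays between -12.3 and 4.82. The precision is limited by the number of arrays. Nothing in the labels says that the arrays of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

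Probe sets for the poly-A spike-in controls, bacterial transcripts added to the RNA before labelling, read higher on the senescent arrays by 0.60 ± 0.17 (log2, SE) in 3 of 3 arrays. The exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 can give. The hybridisation controls differed by 0.09 ± 0.08 and the 18S ribosomal RNA probe sets by -0.02 ± 0.21. The signal of the 3' end over the 5' end of Actb and Gapdh messenger RNA, a measure of RNA integrity, differed by 0.08 ± 0.05 and 0.13 ± 0.06.

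**Figure D1:**
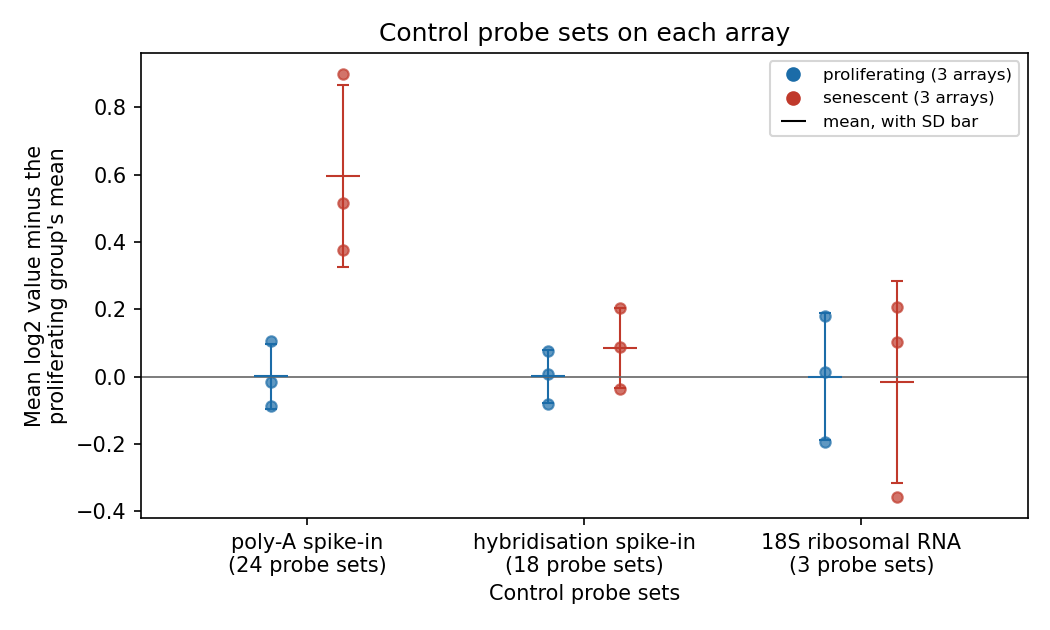
Mean log2 value of the poly-A spike-in, hybridisation and 18S ribosomal RNA probe sets (x axis) on each array minus the proliferating group's mean (y axis), with blue points for proliferating and red for senescent arrays, and ticks with bars for the mean ± SD. The senescent arrays lie above the proliferating ones for the poly-A spike-ins, by 0.60 on average, and overlap them for the other controls.

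The single comparison set senescent against proliferating stellate cells, and asks how the transcriptome differs between cells with these labels. Senescent cells had more RNA of p53 target genes, among them Cdkn1a, which encodes the cell cycle inhibitor p21 (3.34-fold, log2 change 1.74 ± 0.08, SE, n = 3 per group), and more RNA of the collagenase gene Mmp13 (3.57-fold, 1.84 ± 0.11). They had less RNA of genes of cell division, such as the cyclin gene Ccnb2 (2.14-fold, -1.10 ± 0.06), of DNA replication, and of the growth factor receptor gene Pdgfra (4.26-fold, -2.09 ± 0.19, in its brightest probe set). With an estimated correlation between genes, a setting that also leaves camera fewer degrees of freedom, the p53 target list kept its call (adjusted p = 0.045). The cell division and DNA replication lists did not (adjusted p = 0.261 for each). Of 18194 genes, 3645 (20.0%) passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), 1726 of them higher and 1919 lower in senescent cells. Most of these changes were small. Under 1.5-fold were 2462 of them, while 172 genes were at least 2-fold higher and 184 at least 2-fold lower. The senescent and proliferating arrays did not overlap for 6733 genes (37.0%, against 10% by chance). The calls counted as higher were 47.4% of the total here and 63.2% of 3636 calls when each array was centred on the median of genes of middle level. When arrays were scaled to the poly-A spike-ins, an alternative chosen after seeing the data, the median of all genes was -0.60 and 1.14% of calls were higher. All changes below are therefore relative to the bulk of the genes on the array. Without senescent replicate 1 the number of genes called higher was 1128.

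Among the largest falls was Ptn (Entrez gene 19242), which encodes pleiotrophin, a heparin-binding growth factor. Its level was 11.35 ± 0.60 (log2, SD, n = 3) in proliferating and 4.91 ± 0.23 in senescent cells. All senescent arrays lay below the background level of 5.57, the 95th percentile of olfactory receptor probe sets. The probe set read for this gene was thus at least 54.9-fold lower (adjusted p = 1.17e-05). Of the gene's 3 probe sets, 2 passed the threshold, the second with a log2 change of -4.35, and the other gave -0.27. On the same bound, the chemokine gene Cxcl15 was at least 12.2-fold lower, and its dimmer probe set gave a log2 change of -2.79. The oxysterol hydroxylase genes Cyp7b1 and Cyp39a1 were at least 3.69-fold and 3.66-fold lower. Frem1 of the basement membrane was at least 3.68-fold lower, and Tmem178 at least 2.81-fold lower. Il33, which encodes an alarmin cytokine, was 9.38-fold lower, from 11.69 ± 0.10 to 8.46 ± 0.43. Cxcl5, a neutrophil chemoattractant, was 8.27-fold lower, with 1 senescent array below background, and Col6a3, a chain of collagen VI, 6.52-fold lower. The others among the 12 largest falls were Ms4a4d (5.56-fold), Rspo1, an activator of Wnt signalling (5.16-fold), and Islr (5.13-fold).

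The 12 largest rises were ranked by fitted values, as were the falls, so genes known only by a bound have no certain rank. Among them Cyp1a1 (Entrez gene 13076), a xenobiotic-metabolising cytochrome P450, went from 4.87 ± 0.60 (SD, n = 3), below background on every proliferating array, to 8.33 ± 0.17, at least 6.74-fold (adjusted p = 1.21e-04). Ahrr, the repressor of the aryl hydrocarbon receptor that drives Cyp1a1, read 7.29 ± 0.10 in senescent cells (adjusted p = 0.00122), and 2 of the 3 proliferating arrays and their mean lay below background, so no fold is given. Serpinb2, a plasminogen activator inhibitor, was at least 3.10-fold higher. Cxcr6, a chemokine receptor, rose 6.83-fold. Perp, a desmosomal membrane protein, rose 6.54-fold. Crct1 and Ivl, genes of the epidermal differentiation complex, rose 6.36-fold and 6.31-fold, and Ivl encodes involucrin of the cornified envelope. Tll1, a metalloproteinase that processes procollagen, rose 5.41-fold with 1 proliferating array below background, Nipal1 5.41-fold, Nppb, the brain natriuretic peptide gene, 5.20-fold, and Tmcc3 4.44-fold. Apol8 read 8.93 on average in senescent cells and 7.76, 4.89 and 4.14 on the proliferating arrays, 2 of them below background. Its call ended when senescent replicate 1, 2 or 3 was left out (log2 changes of 3.43, 3.26 and 3.32, adjusted p of 0.0533, 0.0752 and 0.0658) and with a robust variance trend (adjusted p = 0.106).

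**Figure D2:**
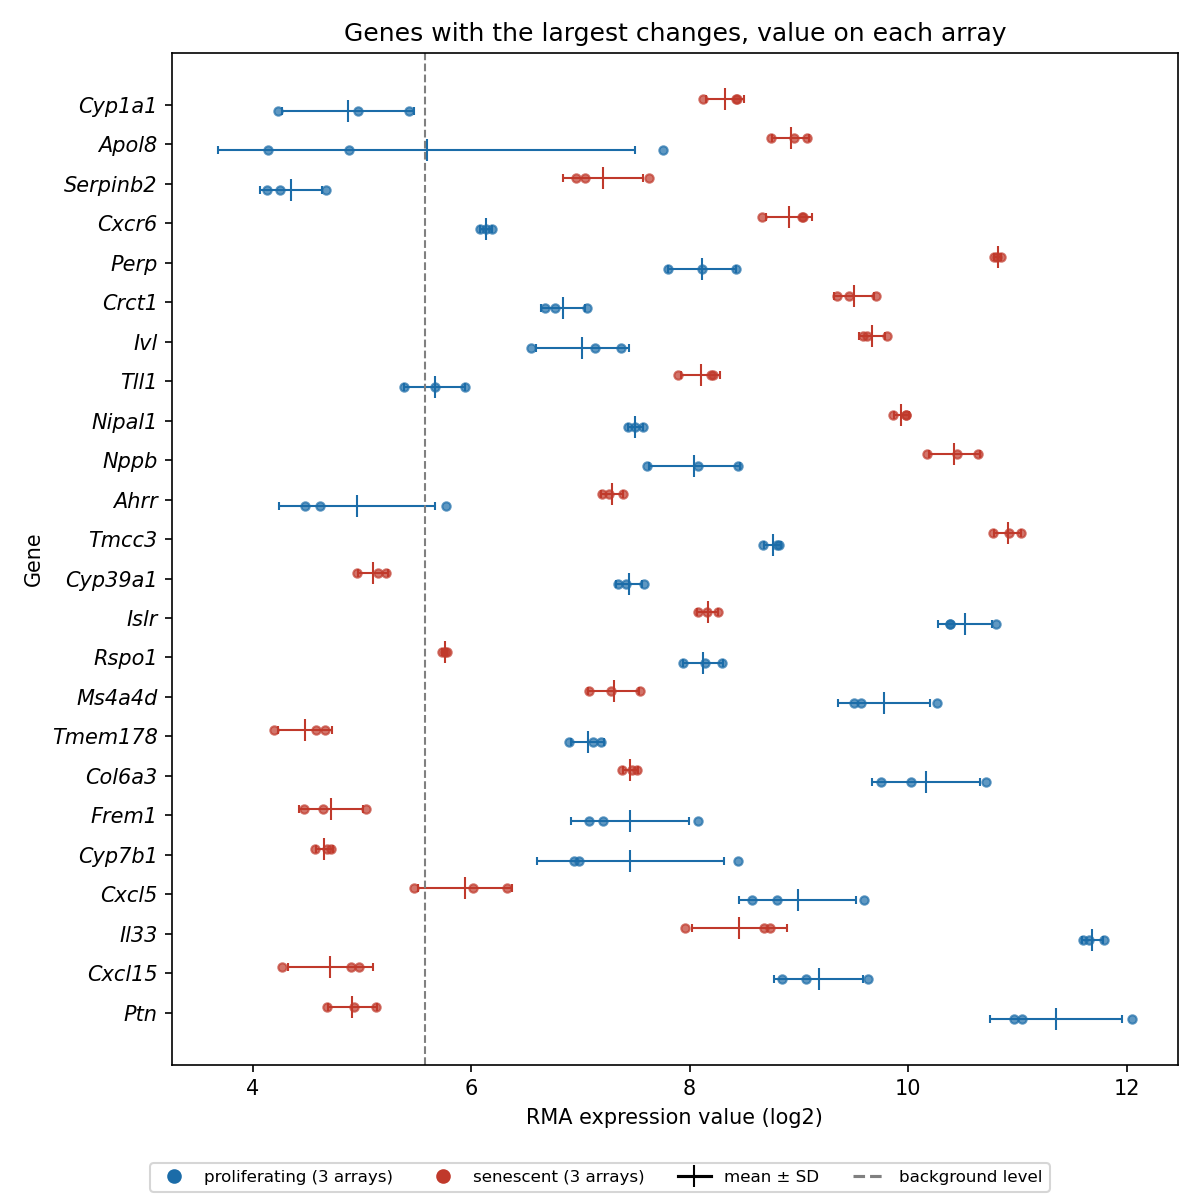
Expression value (RMA, log2, x axis) of the 12 genes with the largest rise and the 12 with the largest fall (y axis) on each array, with points for arrays, blue for proliferating and red for senescent cells, and ticks with bars for the mean ± SD. The 3 senescent arrays of each gene lie apart from the 3 proliferating ones, Apol8 spreads most within a group, from 4.14 to 7.76, and the dashed line is the background level of 5.57.

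Target genes of p53 rose as a group. Of 36 measured, 21 rose and 3 fell, and 24 rose and 3 fell when adjusted over the list alone. Cdkn1a (Entrez gene 12575), which encodes the cyclin-dependent kinase inhibitor p21, went from 11.04 ± 0.05 to 12.78 ± 0.13 (SD, n = 3), 3.34-fold higher with a log2 change of 1.74 ± 0.08 (SE, adjusted p = 1.97e-05). Mdm2, the ubiquitin ligase that targets p53 for degradation, rose 2.32-fold (log2 change 1.21 ± 0.07, adjusted p = 4.41e-05). Pmaip1, which encodes the pro-apoptotic protein NOXA, rose 2.65-fold, and Perp is described above. The 3 that fell were Sesn1, a stress-induced regulator of metabolism, by 0.85 (log2), Cd82, a tetraspanin, by 0.78, and Ddb2, a DNA damage sensor, by 0.73. The median log2 change was 0.45 and the list stood above the other genes (camera, adjusted p = 1.04e-10, and adjusted p = 0.045 with an estimated correlation).

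Cell division genes fell almost throughout. Of 34 measured, 30 fell and 0 rose, and 33 fell when adjusted over the list alone. The median log2 change was -0.61. Ccnb2, a mitotic cyclin, was 2.14-fold lower (log2 change -1.10 ± 0.06, SE). Cenpa, the centromeric histone H3 variant, was 1.93-fold lower, though 1 of its 3 probe sets gave -0.018. The checkpoint genes Mad2l1 and Bub1b were 1.77-fold and 1.75-fold lower. All 34 lay above background on average, and Ccnb2 read 10.29 ± 0.02 (SD, n = 3) in senescent cells. Camera gave an adjusted p of 1.14e-19, and adjusted p = 0.261 with an estimated correlation.

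DNA replication genes also fell. Of 36, 21 fell and 2 rose (24 and 2 when adjusted over the list alone), with a median log2 change of -0.31. Tk1, thymidine kinase, was 1.85-fold lower, and Cdc7, a kinase that fires replication origins, 1.64-fold lower. Tyms, thymidylate synthase, was 1.48-fold lower in 1 of its 4 probe sets, and Rfc5 of the clamp loader 1.47-fold lower. The exceptions were Ccne1, cyclin E1, with a log2 change of 0.42 ± 0.08 (SE), and Rrm2, a ribonucleotide reductase subunit, with 0.35 ± 0.09. The call of Rrm2 ended when proliferating replicate 1 or senescent replicate 1, 2 or 3 was left out (0.26, 0.36, 0.32 and 0.38). Camera gave an adjusted p of 3.15e-08, and adjusted p = 0.261 with an estimated correlation. Of 19 homologous recombination and Fanconi genes, 7 fell and 0 rose (12 fell when adjusted over the list alone), with a median of -0.30. Fanci, Rad54l, Brca1 and Blm fell by 0.55, 0.50, 0.50 and 0.47 (log2). The adjusted p was 4.54e-05, and adjusted p = 0.261 with an estimated correlation.

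Genes of the secretory phenotype, the mix of cytokines, proteases and growth factors that senescent cells are known to release, went both ways. Of 38 measured, 12 rose and 7 fell (13 and 8 when adjusted over the list alone). The collagenase gene Mmp13 rose 3.57-fold, from 7.60 ± 0.11 to 9.44 ± 0.20 (SD, n = 3), and the stromelysin gene Mmp3 3.23-fold, from 7.55 ± 0.06 to 9.24 ± 0.03. The chemokine genes Cxcl5, given above, and Cxcl1 fell, the latter 4.61-fold, from 12.21 ± 0.18 to 10.01 ± 0.07. The median log2 change was 0.058 and the list did not stand apart from other genes (camera, adjusted p = 0.162). It passed when restricted to members above the median level (median 0.24, adjusted p = 0.0412) and with fry, which asks whether members move one way on balance (adjusted p = 0.00829). It did not pass when all genes were filtered at the median level (median 0.24, adjusted p = 0.0668) or at background (median 0.19, adjusted p = 0.114), or with an estimated correlation (adjusted p = 0.773). Nor did it pass with any 1 array left out (medians of 0.043 to 0.11, adjusted p of 0.0886 to 0.302) or with median centring (median 0.13, adjusted p = 0.409).

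Matrix genes were lower on balance. Of 34 fibrillar and basement membrane genes, 15 fell and 7 rose, with the same counts when adjusted over the list alone. The 3 listed chains of collagen VI fell, Col6a3 as given above, Col6a1 2.02-fold and Col6a2 1.97-fold. Loxl1, a collagen and elastin cross-linking enzyme, was 2.06-fold lower. Thbs1, thrombospondin, and Nid1, nidogen of the basement membrane, went the other way and rose 1.90-fold and 1.82-fold. The median log2 change was -0.12 (camera, adjusted p = 0.0191, and adjusted p = 0.261 with an estimated correlation). The call ended among genes above the background level (median -0.10, adjusted p = 0.11) and above the median level (adjusted p = 0.102).

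Genes of stellate cell activation and contraction rose on balance, by small amounts. Of 26, 10 rose and 4 fell (15 and 4 when adjusted over the list alone), with a median of 0.20. Timp1, an inhibitor of metalloproteinases, rose 1.70-fold and Ccn2, connective tissue growth factor, 1.66-fold. The 4 that fell were the growth factor receptor genes Pdgfra, 4.26-fold lower from 10.82 ± 0.44 to 8.73 ± 0.08 (SD, n = 3), and Pdgfrb, 2.46-fold lower, with Tgfb2 and Tgfbr1 of transforming growth factor signalling, by 0.69 and 0.46 (log2). Of the 3 probe sets of Pdgfra, 2 passed, with -2.09 and -1.17, and the other gave -0.89 (limma over probe sets, adjusted p = 0.0688). Camera gave an adjusted p of 0.00279, and adjusted p = 0.261 with an estimated correlation. It was 0.304 for the preset correlation when arrays were scaled to the poly-A spike-ins. In that fit the statistic of every gene carried the shift common to all genes, so this p does not test the relative shift alone.

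Of 25 matrix degradation genes, 5 rose and 6 fell (5 and 8 when adjusted over the list alone), with a median of -0.013 and a camera adjusted p of 0.693. Besides Mmp13 and Mmp3, which the secretory list also holds, Mmp10 rose by 1.12, Mmp14 by 0.43 and Htra1 by 0.30 (log2). Adam12 and Plat, tissue plasminogen activator, were 2.44-fold and 2.29-fold lower, the latter in 1 of 2 probe sets. The call of Htra1 ended without proliferating replicate 3 (0.28).

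Interferon response genes were slightly lower. Of 27, 8 fell and 1 rose, also when adjusted over the list alone, with a median of -0.14. Parp14, Ifih1, Rtp4 and Irf9 fell by 0.92, 0.84, 0.82 and 0.76 (log2). Ifit3 rose by 0.39, a call that ended without senescent replicate 1 (0.35, adjusted p = 0.0502). Camera gave an adjusted p of 0.00741, and adjusted p = 0.261 with an estimated correlation, and the call ended among genes above background (median -0.10, adjusted p = 0.116) and above the median level (adjusted p = 0.153). Of 21 NF-kB target genes, 4 rose and 5 fell (4 and 6 when adjusted over the list alone), with a median of 0.034 and an adjusted p of 0.986. Ptgs2, cyclooxygenase 2, rose 3.11-fold, Tnfaip3, an inhibitor of NF-kB signalling, 2.17-fold, Cd44, the hyaluronan receptor, 1.98-fold, and Bcl2l1 by 0.49 (log2). Bcl3, Irf1, Cx3cl1, Nfkbie and Birc3 fell by 1.23, 0.77, 0.69, 0.59 and 0.53.

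Antigen presentation genes and ligands of natural killer cells went both ways. Of 18 measured, 5 rose and 5 fell (5 and 7 when adjusted over the list alone), with a median of -0.10 and an adjusted p of 0.693. Pvr and Ulbp1, ligands of natural killer cell receptors, rose by 0.78 and 0.52 (log2), the class I genes H2-D1 and H2-K1 by 0.38 and 0.33, and Cd274 by 0.33, with 1 proliferating array of Cd274 below background. The peptide-processing genes Psmb8, Psme1, Erap1, Psmb9 and Tapbp fell by 0.71, 0.69, 0.63, 0.42 and 0.34. Calls ended for Ulbp1 without proliferating replicate 1 (0.46), for H2-K1 (0.32 and 0.30) and Cd274 (0.32 and 0.28) without proliferating replicate 3 or senescent replicate 1, and for Tapbp without proliferating replicate 1 or senescent replicate 1 or 2 (-0.28, -0.33 and -0.30).

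Among 17 measured regulators associated with senescence, 3 rose and 7 fell (3 and 10 when adjusted over the list alone). Besides Serpinb2, Hmga2, a chromatin protein, rose 2.28-fold and Cdkn2b, which encodes the kinase inhibitor p15, 1.45-fold. Hmgb2, a chromatin protein, was 2.06-fold lower and Lmnb1, lamin B1 of the nuclear envelope, 2.02-fold lower, from 11.13 ± 0.20 to 10.12 ± 0.10 (SD, n = 3). The inhibitor genes Cdkn2c and Cdkn1b fell by 0.79 and 0.71 (log2), Dnmt1, Ing1 and Bmi1 by 0.38, 0.38 and 0.35. Cdkn2a, which encodes p16 and p19, had a log2 change of 0.24 ± 0.18 (SE, adjusted p = 0.418). Of the other members, Cdkn1c had -0.71 (adjusted p = 0.106), Hells -0.28 (adjusted p = 0.0551), Cbx7 -0.25 (adjusted p = 0.0863), Sirt1 -0.20, Ezh2 -0.14 and Bhlhe40 0.058. Cdkn1c passed without proliferating replicate 1 or 2 (-0.35 and -0.93, adjusted p of 0.0378 and 0.0455), Hells without senescent replicate 2 (-0.35, adjusted p = 0.0375) and Cbx7 without senescent replicate 3 (-0.33, adjusted p = 0.0375). With array weights Cbx7 and Hells passed (adjusted p of 0.038 and 0.0287), and Hells also with both filters on dim genes, a robust variance trend and cyclic loess (0.029, 0.0345, 0.0187 and 0.047). Outside this list, Glb1, the lysosomal beta-galactosidase behind the standard senescence stain, had -0.11 ± 0.07 (adjusted p = 0.376). The call of Bmi1 ended without any 1 array other than senescent replicate 2 (-0.36 to -0.26). The list's median was -0.28 (adjusted p = 0.0346, and adjusted p = 0.308 with an estimated correlation), and the adjusted p was 0.066, 0.0606 and 0.0712 without proliferating replicate 1, proliferating replicate 3 or senescent replicate 3 (medians of -0.32, -0.28 and -0.26). It was 0.103 with the mean over probe sets, 0.114 among genes above background and 0.0544 among genes above the median level. With scaling to the poly-A spike-ins it was 0.549, which, as for the activation list, does not test the relative shift alone.

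Metabolic lists did not stand apart. Of 30 lysosome genes, 5 rose and 0 fell, also when adjusted over the list alone (median 0.056, adjusted p = 0.272). These were Ctsd, cathepsin D, by 0.82 (log2), Fuca1 by 0.46, Sgsh by 0.38, Atp6v0d1 by 0.30 and Atp6ap1 by 0.27. Calls ended for Sgsh without any 1 array other than proliferating replicate 3 (0.26 to 0.41), for Atp6v0d1 without proliferating replicate 1 or 3 or senescent replicate 1 or 3 (0.28, 0.30, 0.32 and 0.25) and for Atp6ap1 without any 1 array (0.22 to 0.30).

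Of 30 genes of the amino acid and integrated stress response, 6 rose and 5 fell (6 and 6 when adjusted over the list alone, adjusted p = 0.913), and those that rose included Chac1 by 0.71 and Vldlr by 0.62 (log2). Aldh1l2, Pck2, Cebpb, Cth and Psat1 fell by 0.91, 0.82, 0.44, 0.40 and 0.36. Its median of -0.013 and its mean of 0.023 differed in sign, and the test pointed down. The call of Vldlr ended without proliferating replicate 3 (0.53, adjusted p = 0.0534) or senescent replicate 2 (0.56, adjusted p = 0.0695), that of Cebpb without senescent replicate 3 (-0.40), and that of Cth without proliferating replicate 2 or 3 or senescent replicate 1 or 3 (-0.45, -0.31, -0.42 and -0.31).

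Of 41 nuclear-encoded respiratory chain genes, 1 rose and 3 fell (0 and 0 when adjusted over the list alone, median -0.015, adjusted p = 0.693). These were Ndufb3 with 0.22, and Sdha, Atp5c1 and Atp5a1 with -0.25, -0.24 and -0.22. Each of these 4 calls ended without any 1 of the 6 arrays (0.20 to 0.25 for Ndufb3 and -0.28 to -0.20 for the others). Of 19 cholesterol synthesis genes, 5 fell and 1 rose, also when adjusted over the list alone (median -0.17, adjusted p = 0.151). Hsd17b7 rose by 0.65 (log2), and Dhcr7, Stard4, Ebp, Fdft1 and Srebf2 fell by 0.61, 0.52, 0.44, 0.33 and 0.23. Calls ended for Stard4 without proliferating replicate 2 or 3 or senescent replicate 1 or 3 (-0.47, -0.44, -0.55 and -0.39), for Fdft1 without proliferating replicate 3 or senescent replicate 2 (-0.28 and -0.32), and for Srebf2 without any 1 array other than proliferating replicate 1 (-0.25 to -0.22). This list passed without proliferating replicate 1 (median -0.25, adjusted p = 3.67e-04) and with array weights (median -0.24, adjusted p = 0.0289).

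Markers of quiescent stellate cells did not move together. Of 22 measured, 13 above background, 3 rose and 3 fell (3 and 4 when adjusted over the list alone, median -0.023, adjusted p = 0.693). Ecm1, an extracellular matrix protein, rose 2.21-fold, Plin2, which coats lipid droplets, 1.95-fold, and Prnp by 0.53 (log2). Colec11, a collectin, was at least 3.04-fold lower, Cygb, cytoglobin, 2.23-fold lower, and Srebf1 fell by 0.49. The 9 members not above background on average did not pass. Of these, chosen after their values were seen, Lrat, which makes the retinyl esters of vitamin A stores, read 3.55 ± 0.07 (SD, n = 3) and 3.57 ± 0.13 in proliferating and senescent cells, Gfap 5.33 ± 0.15 and 5.31 ± 0.06 and Reln 4.25 ± 0.13 and 4.21 ± 0.14.

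Of the markers of other cells that a stellate culture could hold, those above background on average were 3 of 11 hepatocyte, 7 of 14 macrophage, 3 of 12 endothelial, 3 of 11 lymphocyte and 2 of 8 neutrophil genes. None of these lists stood apart (adjusted p of 0.62, 0.62, 0.449, 0.356 and 0.693, medians of -0.11, 0.067, 0.011, 0.066 and 0.041). Adjusted over the list alone, 0, 1, 1, 0 and 0 members rose and 0 fell. Among members above background, chosen after their values were seen, Cd14 of macrophages read 9.17 ± 0.04 (SD, n = 3) and 8.99 ± 0.12 in proliferating and senescent cells (adjusted p = 0.166). The endothelial genes Emcn and Kdr read 8.69 ± 0.18 and 8.95 ± 0.11 (adjusted p = 0.141) and 7.10 ± 0.18 and 7.25 ± 0.05 (adjusted p = 0.348). Apoa1 of hepatocytes read 6.29 ± 0.21 and 6.03 ± 0.10 (adjusted p = 0.161). Cdh5 of endothelial junctions, below background on every proliferating array, was at least 1.12-fold higher at 5.74 ± 0.07. Csf1r, the macrophage growth factor receptor, rose by 0.35 (log2), a call that ended without proliferating replicate 2 or senescent replicate 1 (0.32 and 0.33). Ahsg of hepatocytes was at least 1.16-fold lower, with all senescent arrays and 1 proliferating array below background. Its call ended without proliferating replicate 2 or 3 or senescent replicate 1 or 2 (adjusted p of 0.0785, 0.0817, 0.119 and 0.122) and with median centring (adjusted p = 0.0604). By limma, 0 lymphocyte and 0 neutrophil genes passed, and the brightest were Cd8a and Cd3e (-0.014 and 0.06) and Camp and Ltf (-0.11 and -0.0026).

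Mesothelial, biliary, fibroblast and smooth muscle markers held members that passed. All 8 mesothelial markers lay above background on average. Of these, Msln and Upk1b rose by 0.79 and 0.43 (log2), while Lrrn4, Wt1 and Gpm6a fell by 1.80, 1.11 and 0.57 (median -0.24, adjusted p = 0.343, 2 rising and 5 falling when adjusted over the list alone). The list passed with fry (adjusted p = 0.0485) and with scaling to the poly-A spike-ins (adjusted p = 0.0353), where the p again does not test the relative shift alone. Upk1b stood at 12.90 ± 0.03 and 13.33 ± 0.01 in proliferating and senescent cells (SD, n = 3). Upk3b stood at 12.61 and 12.42, Gpm6a at 12.11 and 11.54 and Msln at 10.79 and 11.58. Lrrn4, Krt14, Wt1 and Muc16 were dimmer, down to 6.12 for Muc16 in senescent cells. That the cells are stellate cells is taken from the labels and was not tested. Of 8 biliary genes, all keratins among those that passed, Krt18 rose 2.96-fold to 10.96 ± 0.17, Krt19 rose by 0.58 (log2), and Krt7 fell by 0.69 (median 0.046, adjusted p = 0.693, also 2 and 1 over the list alone). Of 8 portal fibroblast markers, Thy1 and Fbln2 rose by 0.79 and 0.50, and Gas6, Col15a1 and Cd34 fell by 1.40, 0.83 and 0.27 (2 and 4 when adjusted over the list alone, median -0.17, adjusted p = 0.343). Of 8 vascular smooth muscle genes, 3 rose and 0 fell (4 and 0 when adjusted over the list alone), Lmod1 by 0.48. The others, Myh11 and Synpo2, lay below background on 6 and 5 of the 6 arrays, so no fold is given, and the call of Synpo2 ended with the mean of its probe sets (adjusted p = 0.202). That list had a median of 0.41 (adjusted p = 0.0266, and adjusted p = 0.261 with an estimated correlation), and its call ended among genes above background (median 0.26, adjusted p = 0.27), among genes or members above the median level (adjusted p of 0.257 and 0.194) and with median centring (adjusted p = 0.0572). The call of Cd34 ended without any 1 array other than senescent replicate 3 (-0.30 to -0.22).

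**Figure D3:**
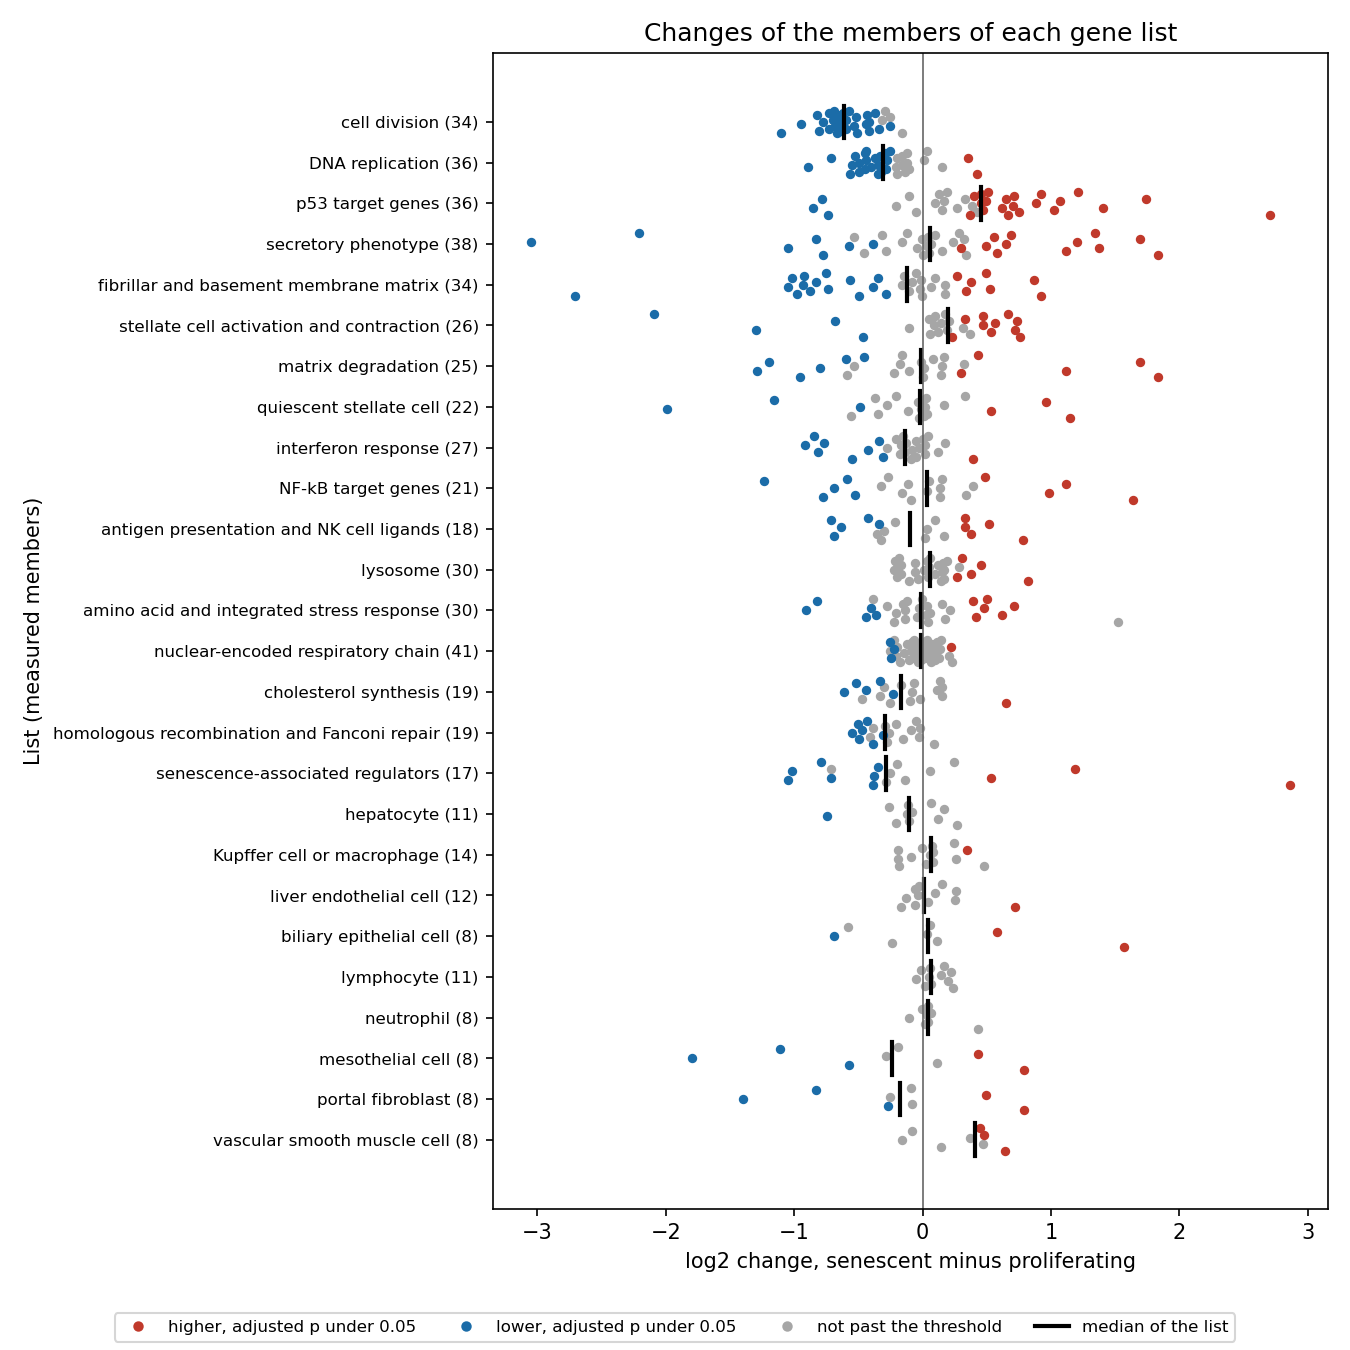
Log2 change, senescent minus proliferating (x axis), of each measured member of the 26 gene lists (y axis, number of members in brackets), with red and blue points for members past an adjusted p of 0.05, grey points for the others and a black bar for the list's median. Cell division genes lie to the left around a median of -0.61, p53 target genes to the right around 0.45, and secretory genes spread from -3.05 to 1.84.

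As a check of the samples, Xist, the RNA of the inactive X chromosome, read 13.45 ± 0.13 and 13.23 ± 0.08 (SD, n = 3) in proliferating and senescent cells (adjusted p = 0.127, and 0.0244 with the mean over probe sets and 0.0348 with a robust variance trend). The Y-linked genes Eif2s3y, Kdm5d and Uty lay below background on all 6 arrays.

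List tests used camera with a preset correlation between genes of 0.01, adjusted over 26 lists of which 9 passed, and of these only the p53 target list also passed with an estimated correlation. Estimating it also lowers camera's degrees of freedom to the 4 residual ones of the fit, which weakens the test by itself. For the p53 target list the estimated correlation was 0.00392, below the preset value, yet its camera p rose from 8e-12 to 0.00173. A call lost in this setting therefore need not be due to correlation between genes. With the preset correlation, other splits of the 6 arrays into 3 and 3 called up to 7 lists. Each of those splits mixed arrays of both groups on each side, so it kept part of the group difference. That number is therefore not a rate expected without such a difference. Reading a gene as the mean of its probe sets ended the calls of Fanci, Ing1, Birc3, Rrm2, Csf1r, Fuca1, H2-D1, H2-K1, Tgfbr1, Fdft1 and Srebf2 (log2 changes of -0.19, -0.21, -0.22, 0.24, 0.22, 0.16, 0.23, 0.10, -0.10, -0.22 and -0.15). It also ended those of Sgsh, Sdha and Atp5a1 (0.21, -0.17 and -0.022) and, as given above, Synpo2. In a fit over all probe sets, only 1 of 2 probe sets passed for each of Cd82, Parp14, Rtp4 and Psmb8, among other genes. The further probe sets of Brca1 gave -0.34, -0.26 and -0.093 and did not pass. Besides Ahsg, median centring ended the calls of Tapbp, Bmi1, Cth, Stard4, Fdft1, Srebf2, Sdha, Atp5c1, Atp5a1 and Cd34 (-0.27, -0.28, -0.34, -0.45, -0.26, -0.16, -0.18, -0.17, -0.15 and -0.20), and cyclic loess that of Cd34 (-0.26). Doxycycline, the hairpin and the growth state followed the same split of the samples, so their effects cannot be separated in this design.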

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

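The tests of the poly-A controls in this part were chosen after the result was seen. The poly-A spike-in probe sets, which belong to no comparison of genes, read higher on the senescent arrays by 0.60 (log2, SE 0.17), with 24 of 24 probe sets higher and each senescent array above each proliferating one. The hybridisation controls were also higher in 18 of 18 probe sets, by 0.085 (SE 0.083), with 2 of 3 senescent arrays above each proliferating one. The poly-A shift exceeded that of the hybridisation controls by 0.511 (95% interval 0.0877 to 0.935), so those controls did not share it in full. Quantile normalization removes brightness shared by a whole array, so this difference cannot test brighter senescent arrays as a cause. Less polyadenylated RNA in the total RNA of senescent cells may account for the shift and stays open, because the poly-A shift exceeded that of the 18S probe sets by 0.613 with an interval of -0.294 to 1.52. A difference in the amount of spike-in added was not tested.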

How the results depend on the processing

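Scaling to the poly-A spike-ins was chosen after the data were seen, and the other settings before. Where nothing else is said, the cause was not tested. Of the 119 genes that the naming rule took and that passed, 100 kept their call and 0 changed sign in each setting in which they were refitted gene by gene, leaving out each array included. Those were the settings other than the unmoderated, 1.5-fold and poly-A ones, and genes under a filter on dim genes were not refitted with it. Testing probe sets in place of genes, which tests more features, gave 2699 higher and 2880 lower, 340 and 334 of them at least 2-fold. Without variance moderation 1077 were higher and 1148 lower. A test against a 1.5-fold change, which asks for more, gave 134 higher and 105 lower, 101 of these at least 2-fold lower. Leaving out 1 array gave 1128 to 1562 genes higher. The matrix list shifted by -0.10 under both filters on dim genes (adjusted p of 0.102 and 0.11). With an estimated correlation, and the fewer degrees of freedom that come with it, calls ended for cell division, DNA replication, matrix and activation genes. Their shifts were -0.61, -0.31, -0.12 and 0.20 (adjusted p of 0.261 each). Secretory genes passed with fry at 0.058 (adjusted p = 0.00829) and, among members above the median level, at 0.24 (adjusted p = 0.0412). Poly-A scaling moved the median of all genes to -0.60, by its construction, and gave 175 genes higher and 15150 lower, 40 and 1277 of them at least 2-fold, with activation genes at 0.20 relative to other genes (adjusted p = 0.304). Small shifts that had not passed changed sign. With the mean over probe sets these were the stress response list at 0.037, Cd8a at 0.011 and Ttr at 0.074, and Ccn1, which had passed, went to -0.33 and also lost its call without proliferating replicate 3 (0.29, adjusted p = 0.0666) or senescent replicate 2 (0.31, adjusted p = 0.0529). With median centring, which moved the median of all genes to 0.067, they were the stress response at 0.056, matrix degradation at 0.056, quiescent markers at 0.046, the respiratory chain at 0.053, Cd8a at 0.055 and Ltf at 0.066. With filters on dim genes or members they were NF-kB targets at -0.027, macrophage markers at -0.079 and biliary markers at -0.062. Eif2s3y was -0.0059 with cyclic loess and -0.040 with array weights, which put endothelial markers at -0.015. Over the fits that left out 1 array, ranges crossing 0 were -0.048 to 0.22 for Bhlhe40, -0.018 to 0.10 for Cd3e, -0.088 to 0.045 for Cd8a, -0.095 to 0.13 for Eif2s3y, -0.20 to 0.10 for Kdm5d and -0.070 to 0.095 for Ltf. For lists they were -0.037 to 0.074 for NF-kB targets, -0.061 to 0.016 for the stress response, -0.038 to 0.065 for endothelial, -0.0089 to 0.15 for lymphocyte and -0.0092 to 0.070 for neutrophil markers, and -0.079 to 0.017 for matrix degradation. With the replicate number as a block 2935 genes passed, 2834 of them shared with the fit without it. The block ended calls, among them those of Atp6v0d1, Bmi1, Cth, Stard4 and Sgsh (adjusted p of 0.0567, 0.058, 0.0858, 0.0534 and 0.0674). Same-numbered arrays did not deviate together (correlations of 0.094, -0.0684 and -0.153). This cannot tell whether a number marks a shared animal, culture or day, which the titles do not say. Signal over background limits the dimmer genes, since 3430 of the 3645 calls lay above the background level on average.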

Other observations

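The tests of cornified envelope, aryl hydrocarbon receptor and NRF2 targets and the splits of the arrays were chosen before their results were seen, those 3 lists having been drawn up after the largest changes were known, and the test of mesothelial markers, and the restriction of the 3 lists to members above background, after the results were seen. Genes in this part that are not given above were chosen after their values were seen. Of the fibrillar collagen genes, Col1a1, Col1a2 and Col3a1 fell by 0.56, 0.49 and 0.93 (log2), while Acta2, the smooth muscle actin of activated stellate cells, had a change of 0.12 that did not pass. Il6, a cytokine of the secretory phenotype, had -0.54 and did not pass. Immediate-early genes, which respond within minutes to stimulation, had array medians of 10.07, 8.77 and 8.43 in proliferating and 9.71, 9.64 and 9.61 in senescent cells (list camera adjusted p = 0.665).

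Beside Ivl and Crct1, the epidermal genes Lce1h and Sprr2h were 3.65-fold and 3.54-fold higher, and the keratin genes Krt18 and Krt19 rose as given above. Lce1h and Sprr2h were read from probe sets that can bind several transcripts (suffix _x_at and _s_at), so which close relatives rose is uncertain. Of 30 further measured members of the cornified envelope list, 16 lay above background, and the others cannot show a small rise. The 30 had a median of 0.027 and a camera p of 0.357 (adjusted p = 0.713 over the 4 lists of this kind), and the 16 a median of 0.053, quartiles of -0.034 and 0.235 and a camera p of 0.361 (adjusted p = 0.722). This argues against a rise of these 16 together by about as much as Ivl (2.66), and a smaller rise stays open. Pkp1 and Dsp rose by 0.65 each, Lce1f passed from below background on every proliferating array to 5.67, and Lor and Ppl fell by 0.39 and 0.62, where the calls of Dsp (0.59 and 0.62 without senescent replicate 1 or 2) and Lor (-0.41 to -0.33 without any 1 array other than proliferating replicate 3, -0.32 with median centring and -0.34 with array weights) ended. The mesothelial markers, all above background, did not rise together and ran from -1.80 for Lrrn4 to 0.79 for Msln, with 2 called higher and 3 lower. Changes of these genes within cells would also give mixed shifts, so the markers cannot decide whether the share of mesothelial cells differed. A rise limited to part of the epidermal genes may remain and was not tested.

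Cyp1a1, Ahrr and Nqo1, a quinone reductase that was 3.44-fold higher, are all known targets of the aryl hydrocarbon receptor. The 5 other measured targets had a median of -0.057 (camera p of 0.964, adjusted p = 0.99), and the 4 of them above background a median of 0.18 with quartiles of -0.30 and 0.44 (camera p of 0.756, adjusted p = 0.99). The largest rise among the 5 was 0.52, below that of Nqo1 (1.78). So few genes cannot decide on a wider response of the receptor. Cyp1b1 was also very bright, at 13.04 in proliferating cells, where RMA compresses changes. Of the 5, Tiparp and Cyp1b1 rose by 0.52 and 0.41 and Aldh3a1 fell by 1.02. The call of Tiparp ended without any 1 array other than proliferating replicate 1 (0.42 to 0.55) and with the mean over probe sets (adjusted p = 0.0854). Of the other measured NRF2 targets, all 11 above background, the median was -0.11 with quartiles of -0.19 and 0.28 (camera p of 0.99, adjusted p = 0.99), which argues against a rise of these together by about as much as Nqo1. Of them, Srxn1, Txnrd1 and Taldo1 rose by 0.71, 0.42 and 0.41, and Fth1 and Gstm1 fell by 0.23 and 1.21, though the call of Fth1 ended without any 1 array (-0.24 to -0.20), with the mean over probe sets (-0.19) and with median centring (-0.16). A response of a subset of targets, or an effect of doxycycline, may account for the 3 genes and cannot be separated from the growth state here.

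In 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, each count of genes and of lists was as large as observed. The real split gave 1726 genes higher and 1919 lower, 172 and 184 of them at least 2-fold, and 9 lists, against at most 0 genes in each class and 7 lists in any other split. Every other split mixed arrays of both groups on each side. The group difference thus partly stayed in each contrast and otherwise widened the spread within the sides. The 0 genes and 7 lists are therefore not counts expected by chance. With 10 splits no share under 0.05 can be reached.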
